A study of Mus musculus with 20 samples.

How the data were processed

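CD45-positive cells from tumours of a mouse melanoma model with mutated Nf1 were profiled by droplet single-cell RNA sequencing, in 10 gene expression libraries with 1 library per treatment and day. The 5 libraries without lead-in were untreated at day 0, trametinib at day 3 and day 7, and trametinib plus anti-PD-L1 at day 3 and day 7. The 5 libraries with an anti-PD-L1 lead-in matched them 1 to 1. The 10 T cell receptor libraries of the same samples were not analysed here, because no processed file of theirs was among those used here.

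The deposited values are on a natural log scale: for each gene in each cell the authors gave the natural log of 1 plus 10000 times the gene's unique molecular identifiers (UMIs) divided by the cell's total. Undoing the log gave 10000 in every cell. Libraries were made with a 10x Genomics 5 prime kit, per the labels' protocols. Cell Ranger and Seurat were used, per the submitters' processing notes; their versions and the filters on cells and genes are not given in the sources used here. The genome build is named as GRCh38, per the submitters' processing notes, although the gene symbols in the deposited table are mouse ones, so no coordinates are reported. The table holds 14854 genes and 53841 cells. Every cell had at least 501 detected genes and at most 20.0% mitochondrial UMIs, and every gene was detected in at least 3 cells. Each cell carries the number of its library in its name, and that number was matched to the sample number in the labels; 0 cells stayed unmatched. Genes are named by the symbols of the table.

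Because each cell's smallest step equals 1 UMI, whole UMIs were recovered: 100% of the 111508957 values above 0 came out whole within a tolerance of 0.01. Total UMIs per library ranged from 23053430 to 66252244 and cells per library from 1824 to 7597. The design had named a count model for raw counts and limma for log-normalised values. The table held the latter, so limma gave the main results, and the recovered UMIs entered only as an alternative and for intervals.

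Cells were clustered on the deposited values with scanpy 1.11.5 and leidenalg 0.10.2, using 2000 variable genes, 30 principal components, 20 neighbours and a Leiden resolution of 1.0, with no correction between libraries. Antigen receptor, mitochondrial, ribosomal protein and haemoglobin genes, Xist and Y-linked genes were left out of the variable genes. T and natural killer (NK) cells were clustered again at a resolution of 1.5, and small myeloid clusters at 0.6. A cluster was named when at least 3 markers of a fixed list were 2-fold above the other clusters. A cluster stayed unnamed when it held genes of 2 lineages, a median mitochondrial share above 5%, a median UMI count under 0.333 of its library's, too few markers, or a T cell name without CD3 genes. The neutrophil cluster was an exception and kept its name at 0.268 of its library's median UMI count. Clusters led by cycling genes formed a cycling lymphoid and a cycling myeloid class, which were left out of the gene tests. The markers were fixed in advance, but these naming rules were set after the clusters had been seen, so the share of unnamed cells is given per library. Class names stand for clusters that resemble the type ("macrophage-like" and so on). Doublets were scored with Scrublet and kept in the main results. Its automatic threshold called 0 to 4 cells per library and was judged not to have worked, so the cells with the highest scores were called, 0.8% per 1000 cells of the library. That rule was chosen after the failure was seen.

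For each library and class with at least 20 cells, the linear-scale values were averaged over cells and scaled to CPM. A class was tested when at least 8 libraries held it. limma 3.58.1 (R 4.3.3), with a mean-variance trend, was fitted to log2(CPM + 1), so fold changes understate the change of low genes. Genes entered with a mean of at least 10 CPM and at least 50 UMIs summed over libraries. The additive model had terms for the lead-in, trametinib day 3, trametinib day 7 and anti-PD-L1 given with trametinib. All libraries share 1 estimate of the spread, with 3 to 5 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, from limma unless another tool is named. Interactions were added to the model 1 at a time, in the classes that all 10 libraries hold; this restriction was made after fits on fewer libraries had been seen. Gene lists were tested with camera at the preset inter-gene correlation of 0.01, and adjusted over the lists of a class. The 23 lists, of T cell, macrophage, interferon, antigen presentation, metabolic and stress genes among others, were each tested where at least 3 members were measured. Shares of classes were compared with an exact two-sided sign-flip permutation test over 5 matched pairs for the lead-in, and over 4 matched pairs for anti-PD-L1 and for day 7 against day 3, with 0.5 cells added to each count. Shares of single libraries carry exact binomial 95% intervals and summed UMIs exact Poisson intervals; both cover counting error only.

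Lists, markers, comparisons, tests and most alternatives were fixed before the data were examined. Genes are named by a rule fixed at the same time. For the lead-in, it names the 5 highest and 5 lowest log2 fold changes among genes past the threshold with the same sign in every matched pair, then genes of smallest p up to 3 per direction, said not to pass. For the other contrasts it names 3 per direction. It adds up to 2 members at each end of a reported list and 21 genes that are always followed. Antigen receptor, mitochondrial, Xist, Y-linked and predicted genes are not named by rank. Between single libraries it names the 3 largest ratios in each direction among genes with at least 50 CPM in either library; only macrophages and only the 3 libraries of a single treatment are given.

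The test was tried on simulated data with 200 changed genes per class. For the lead-in, it recovered 98.5% of macrophage genes and 76.1% of CD8 T cell genes changed by 1 log2 unit. In regulatory T cells it recovered 11.9% of genes changed by 1 log2 unit and 81.8% of those changed by 3. Between 0 and 11.3% of the calls were false over all classes and contrasts. A shifted list was called in 10 of 10 classes, beside up to 3 unshifted lists. The simulated noise was independent between genes and between libraries. These rates therefore do not carry over to data with correlated genes or differences shared by sets of libraries.

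Alternatives were quantile normalization, no filter on low values, each library left out, cell classes from marker scores, a block for the matched backgrounds, pseudocounts of 0.1 and 10, stricter cells (at least 500 genes and under 10% mitochondrial UMIs, which left 51886 cells), called doublets removed (51212 cells left), classes summed at their mean weight, and, for lists, camera with an estimated correlation and fry. For shares they were clustering at resolutions of 0.5 and 2.0, other denominators and limma on log2 odds. Added after the data had been seen were a term for libraries 7 to 10, 2 fits that leave out 2 libraries each, summed UMIs, and a total without unnamed clusters. With the term for libraries 7 to 10, the lead-in estimate is the lead-in day 0 library against the untreated one alone. Figures were drawn with matplotlib 3.10.9; other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.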

Results

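Tumour-infiltrating CD45-positive cells were sequenced one by one from a mouse melanoma model with mutated Nf1. The design asks what an anti-PD-L1 lead-in, given before the MEK inhibitor trametinib, does to immune cells in the tumour. It crosses the lead-in with 5 backgrounds: no drug at day 0, and trametinib alone or trametinib plus anti-PD-L1 at day 3 and day 7. Each combination was 1 library. The lead-in was therefore compared over 5 matched pairs of libraries, anti-PD-L1 given with trametinib over 4 pairs, and day 7 against day 3 over 4 pairs. Cells per library numbered 6308 in the untreated library, 4830 with trametinib at day 3, 4767 with trametinib at day 7, 1824 with trametinib plus anti-PD-L1 at day 3, and 5072 with trametinib plus anti-PD-L1 at day 7. With the lead-in they numbered 2144 at day 0, 7040 and 7597 with trametinib at day 3 and day 7, and 7173 and 7086 with trametinib plus anti-PD-L1 at day 3 and day 7. Total UMIs ranged from 23053430 (trametinib plus anti-PD-L1 at day 3) to 66252244 (lead-in, trametinib plus anti-PD-L1 at day 7), and the median per cell from 4176 to 11500.

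Macrophage-like cells were the most abundant class in most libraries, from 12.8% of cells (lead-in, trametinib at day 7) to 69.3% (trametinib plus anti-PD-L1 at day 3; exact binomial 95% interval 67.1 to 71.4). CD8 T cells ranged from 2.74% to 35.9% in the same libraries in reverse order. Fibroblast-like cells made up 13.5% of the lead-in day 0 library and 0.0658% of the lead-in trametinib day 7 library, although the cells had been sorted on CD45, and shares of all other classes are of a total that includes them. Unnamed clusters held 6.87% to 26.6% of cells. In the trametinib plus anti-PD-L1 day 7 library, 23.4% of cells fell in clusters with a high mitochondrial share.

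Trametinib blocks the kinase that activates ERK, so the transcripts that ERK induces check the labels of the drug. In macrophages the mean log2 level of the ERK output genes was 6.43 in the untreated library. It was 5.41 ± 0.21 (SD, n = 7) in the trametinib libraries other than the one labelled trametinib day 3, which stood at 6.24. The library labelled lead-in day 0, which had received no trametinib per its label, stood at 5.37. Ccnd1, the cyclin D1 gene, stood at 240 CPM in untreated macrophages, 257 in the library labelled trametinib day 3 and 33.0 in the library labelled lead-in day 0. Its values in the other trametinib libraries ran from 19.7 to 80.7 CPM. In macrophages, ERK output in these 2 libraries goes against their labels, and every contrast below draws on 1 or both of them. In CD8 T cells the library labelled lead-in day 0 lay above the untreated one (0.29). The check tells nothing there, since the untreated library itself lay at -0.10 from the mean of those 7 trametinib libraries. Without the 2 libraries the lead-in sum of 99 calls given below became 713, the anti-PD-L1 sum of 1 became 4 and the trametinib sum of 0 became 567. Most of the rises to 713 and 567 came from monocytes, a class held by 8 libraries before these 2 were left out. Lead-in calls fell in CD4 T cells, regulatory T cells and activated dendritic cells. With lead-in day 0 left out, the lead-in libraries were libraries 7 to 10, and the lead-in cannot be told apart from that set.

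With against without the lead-in, 2 genes each passed in macrophages and CD8 T cells, 37 in CD4 T cells, 29 in regulatory T cells and 24 in activated dendritic cells. Macrophages had more Vcam1, the adhesion molecule that binds integrins on T cells and monocytes. CD8 T cells and CD4 T cells both had more Tsc22d3, which encodes the glucocorticoid-induced leucine zipper. CD4 T cells and regulatory T cells had less of the transcripts that macrophages express at high levels, C1q and major histocompatibility complex (MHC) class II genes among them. In activated dendritic cells Fscn1, which encodes an actin-bundling protein of their dendrites, was higher and the interferon-induced chemokine gene Cxcl9 lower.

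In macrophages, 2 of 7191 genes passed the threshold and 1010 had an unadjusted p under 0.05. Vcam1 rose by a log2 fold change of 1.61 (SE 0.18, adjusted p = 0.0176), from 33.3 ± 15.0 to 106 ± 46.7 CPM (SD, n = 5 each), and was higher with the lead-in in 5 of 5 pairs. Ccnb1ip1, which encodes a ubiquitin ligase, fell from 31.6 ± 13.5 to 8.88 ± 9.28 CPM (adjusted p = 0.0176) in 5 of 5 pairs; it is 1 of 4 genes that set libraries 7 to 10 apart from the others in nearly all classes. Next by p, and not past the threshold, came Cryba4 (0.93, adjusted p = 0.112) and Sumo3 (0.60, adjusted p = 0.128) upwards, and the fibronectin gene Fn1 (-1.32, adjusted p = 0.101) and AY036118 (-1.41, adjusted p = 0.101) downwards. Of the 21 genes always followed, 12 were measured and none passed. Arg1 was lowest at -1.42 (adjusted p = 0.309), lower in 4 of 5 pairs, and Cxcl9 stood at -0.94 (adjusted p = 0.496). Vcam1 lost its call without trametinib day 3, trametinib day 7, or the lead-in trametinib plus anti-PD-L1 day 3 library, with adjusted p up to 0.0691. It also lost it with a term for libraries 7 to 10. That term leaves the lead-in estimate to the day 0 pair, 1 library against 1, so this loss decides nothing on a set effect. Ccnb1ip1 lost it without trametinib day 3, trametinib day 7, lead-in trametinib day 3, lead-in trametinib plus anti-PD-L1 day 3 or trametinib plus anti-PD-L1 day 7, with adjusted p up to 0.0982. The 2 calls became 21 without trametinib day 3 and lead-in day 0 together, 9 without the untreated or the lead-in day 0 library, and 4 without trametinib plus anti-PD-L1 day 3 or lead-in trametinib plus anti-PD-L1 day 7. The macrophage cells lay mainly in cluster a3 in the untreated and trametinib day 3 libraries, in a5 in lead-in trametinib day 3, in a2 in lead-in trametinib day 7, in a8 in trametinib day 7 and in both trametinib plus anti-PD-L1 day 7 libraries, and in a11 in the 3 others.

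**Figure D1:**
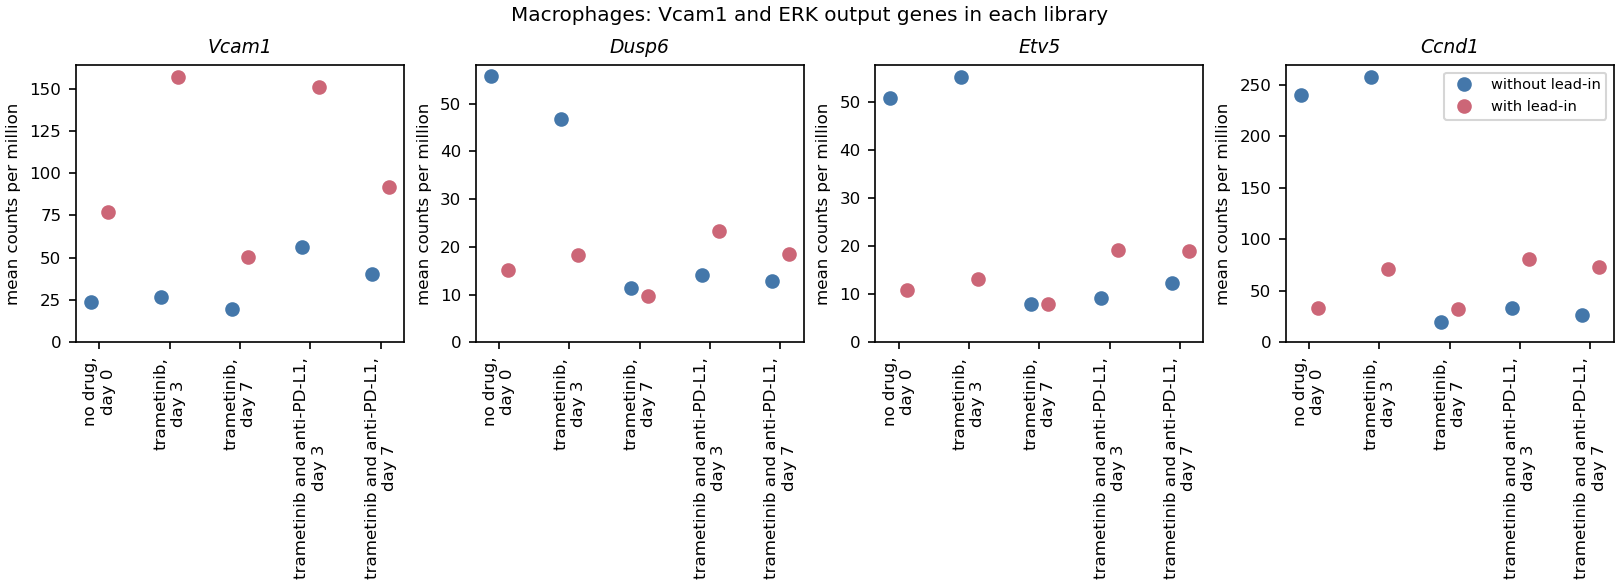
Macrophage levels of Vcam1 and the ERK output genes Dusp6, Etv5 and Ccnd1 in each of the 10 libraries, in mean CPM, by background, without and with the lead-in. Vcam1 is higher with the lead-in in all 5 backgrounds, and the ERK output genes are high in the libraries labelled untreated and trametinib day 3.

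Among 7229 genes of CD8 T cells, 2 passed, with 1183 at an unadjusted p under 0.05. Tsc22d3 rose by 1.27 (SE 0.17, adjusted p = 0.0394) in 5 of 5 pairs, from 202 ± 40.4 to 497 ± 146 CPM. Ccnb1ip1 fell by 2.33 (SE 0.30, adjusted p = 0.0394) in 5 of 5 pairs. Zfp36l2, an RNA-binding regulator of quiescence, was 0.77 higher and B4galt5 was lower by -1.06 (adjusted p = 0.0570 for both), neither past the threshold; Ctbp1 (0.72, adjusted p = 0.0872) and Hnrnph1 (-0.77, adjusted p = 0.0570) did not pass either. Markers of exhaustion, memory and killing showed no call: Pdcd1 stood at 0.34 (adjusted p = 0.644), Tcf7 at 0.26, Gzmb at 0.18 and Ifng at -0.42. In CD4 T cells 37 genes passed, 11 higher and 26 lower, each in the same direction in 4 of 4 pairs. The 5 highest were Tsc22d3 (1.64, adjusted p = 0.0341), Tubb4b (1.31), Socs3 (1.29), Gramd3 (1.28) and Sertad1 (1.17). The 5 lowest were Tyrobp (-3.58), Fcer1g (-3.46), Alox5ap (-3.14), C1qa (-2.51) and H2-Eb1 (-2.38). Tsc22d3 lost its call in both T cell classes without trametinib day 3, lead-in trametinib day 3, trametinib plus anti-PD-L1 day 7, or either lead-in trametinib plus anti-PD-L1 library. Its adjusted p then reached 0.212 in CD8 T cells and 0.329 in CD4 T cells. The 2 calls in CD8 T cells became 0 without any of these 5 libraries, 1 without lead-in trametinib day 7, 13 without trametinib plus anti-PD-L1 day 3, 42 without lead-in day 0 and 44 without the untreated library. Blocking on the matched backgrounds left 0 calls in CD8 T cells, CD4 T cells and macrophages, and so did no filter or marker-score classes in CD8 T cells and macrophages, a pseudocount of 0.1 in CD8 and CD4 T cells, and summed UMIs in CD4 T cells. The 37 calls became 0 without any of the first 3 of these libraries or lead-in trametinib plus anti-PD-L1 day 3, 5 without lead-in trametinib plus anti-PD-L1 day 7, 18 without lead-in trametinib day 7, 134 without the untreated library and 170 without lead-in day 0. The largest cluster of CD8 T cells was t3 in untreated and trametinib day 3 (34.1% in the latter), t0 in trametinib day 7, t11 in trametinib plus anti-PD-L1 day 3, t9 in trametinib plus anti-PD-L1 day 7 (45.8%), t15 and t6 in lead-in trametinib day 3 and day 7, and t9 in the other 3 lead-in libraries. CD4 T cells lay mainly in cluster t14 in both lead-in libraries with trametinib alone (70.2% and 75.0%) and in t5 in the others.

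Regulatory T cells had 29 calls among 5894 genes, 10 higher and 19 lower. S100a4 (1.61, adjusted p = 0.0239), the arginine synthesis gene Ass1 (1.55), the actin gene Actg1 (1.11) and the ribosomal protein genes Rplp0 (1.1) and Rps7 (1.03) rose the most, beside an immunoglobulin gene left unnamed by the rule. C1qc (-3.39), H2-Aa (-2.99), Lyz2 (-2.84, adjusted p = 0.00233), H2-Ab1 (-2.79) and Tyrobp (-2.79) fell the most. The lineage genes Foxp3 (0.02) and Il2ra (-0.19) showed no call. Lyz2 passed in each of the 8 fits that leave out a library, but not with no filter on low values (adjusted p = 0.539) or marker-score classes (-0.74, adjusted p = 0.344), which left 0 and 2 calls in the class. The 29 calls became 3 without trametinib day 3, 5 without lead-in trametinib plus anti-PD-L1 day 7, 6 without trametinib plus anti-PD-L1 day 7, 15 without lead-in trametinib plus anti-PD-L1 day 3 and 84 without trametinib day 7. Activated dendritic cells had 24 calls, 6 higher and 18 lower. Fscn1 rose by 0.92 (SE 0.13, adjusted p = 0.0113), from 4003 ± 626 to 7554 ± 1144 CPM, in 4 of 4 pairs. Crispld2 summed to 73.0 CPM with the lead-in (264 UMIs over 4 libraries) and 9.23 without it (18 UMIs, all in 1 of 5 libraries). Asprv1 had 132 UMIs with the lead-in and 0 without it, at least 23.7-fold higher against a floor of 3 counts over the group. Ccni (1.11) and Pcbp2 (0.79) also rose. Cxcl9 fell by 2.55 (SE 0.35, adjusted p = 0.0112), from 130 ± 40.7 to 21.5 ± 7.02 CPM. The interferon-induced genes Oasl1 (-2.04) and Helz2 (-1.98), AY036118 (-1.94) and Kmt2d (-1.82) fell with it. The class joins 2 clusters, m3 and m4, and m4 held 89.5% of its cells in lead-in trametinib day 3, 89.3% in lead-in trametinib day 7 and 0 of 26 in trametinib plus anti-PD-L1 day 3. Within m3, the Fscn1 mean was 6929 ± 1166 CPM with the lead-in (SD, n = 3 libraries with 20 cells) and 3605 ± 1022 without it (n = 5), and within m4 it was 8138 ± 1448 and 4328 ± 919 (n = 3 each), values with no test. Cxcl9 was lower with the lead-in within m3 (39.6 ± 16.4 against 166 ± 61.3 CPM) but not within m4 (8.31 ± 3.07 against 4.33 ± 7.50). With no filter on low values (adjusted p = 0.246 for both) and with marker-score classes (Cxcl9 -0.23, adjusted p = 0.921; Fscn1 0.76, adjusted p = 0.310) both lost their call, and the 24 calls became 1 under each. Of the fits that leave out a library, Cxcl9 lost its call without lead-in trametinib plus anti-PD-L1 day 7 (adjusted p = 0.0597), and Fscn1 without that library or lead-in trametinib day 3 (up to 0.0985). The count of 24 became 2 without lead-in trametinib plus anti-PD-L1 day 7, 9 without lead-in trametinib day 3, 11 without trametinib day 3, 12 without lead-in trametinib day 7 and 55 without trametinib plus anti-PD-L1 day 3.

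B cells had 2 calls, both lower, with AY036118 at -1.84 (adjusted p = 0.04). NK cells had 2, both lower, with AY036118 at -1.68 (adjusted p = 5.75e-04). Type 2 conventional dendritic cells had 1, the mitochondrial gene mt-Atp8, named here after its value was seen. AY036118 and mt-Atp8 were each called lower in 5 classes, and both are among the 4 genes that set libraries 7 to 10 apart. Monocytes had 0 calls from limma and 808 genes at an unadjusted p under 0.05; the count was 668 without trametinib day 3 and lead-in day 0, 81 with marker-score classes, 28 without trametinib day 7 and 18 without lead-in trametinib day 7. In B, NK and regulatory T cells and in both dendritic cell classes the lead-in day 0 library held under 20 cells. There the lead-in libraries are libraries 7 to 10, and the lead-in cannot be told apart from that set. The same holds in every class for fits without the untreated or the lead-in day 0 library. The model meets a single day 0 library exactly. Its lead-in estimate then compares libraries 7 to 10 with the trametinib libraries without the lead-in. Summed over classes, 99 calls were made, 29 higher and 70 lower. The sum became 19 without lead-in trametinib plus anti-PD-L1 day 7, 20 without trametinib day 3, 37 without trametinib plus anti-PD-L1 day 7, 39 without lead-in trametinib day 3, 59 without lead-in trametinib plus anti-PD-L1 day 3, 153 without trametinib plus anti-PD-L1 day 3, 250 without the untreated library, 279 without lead-in day 0 and 683 without trametinib day 7.

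With all cells of a library summed, 0 of 7905 genes passed for the lead-in by limma, and 950 had an unadjusted p under 0.05. Highest by p were Tsc22d3 (1.11, adjusted p = 0.408), the macrophage chitinase-like gene Chil3 (1.67) and the lipase gene Pnpla2 (0.68), and lowest Ccnb1ip1 (-2.26, adjusted p = 0.209), Tnip3 (-1.09) and AI504432 (-1.14). Arg1, which degrades arginine, was lower in 5 of 5 pairs (-1.65, adjusted p = 0.408). The count was 144 without the untreated library and 133 without lead-in day 0. Both fits compare libraries 7 to 10 with the trametinib libraries without the lead-in. They are therefore not separate checks, and they do not tell the lead-in from that set.

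By camera with its preset correlation, genes induced by interferon-gamma, MHC class II genes and genes of hypoxia and glycolysis were called lower in macrophages of lead-in tumours (adjusted p = 0.684 for each with an estimated correlation). In T cells MHC class II and C1q genes were called lower, and in CD4 T cells and regulatory T cells naive genes higher (adjusted p = 0.386 to 0.892 with an estimated correlation). In monocytes every measured type I interferon response gene had a lower estimate, with none past the threshold over all genes (list adjusted p = 0.138 with an estimated correlation). Both trametinib plus anti-PD-L1 libraries without the lead-in held 13 monocytes and were left out. This leaves 3 matched pairs, among them those of the libraries labelled trametinib day 3 and lead-in day 0.

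In macrophages 25 of 26 interferon-gamma response genes were lower with the lead-in (camera adjusted p = 0.00158; 0.684 with an estimated correlation), with Ciita, the activator of MHC class II genes, at -1.03. All 8 MHC class II genes were lower (adjusted p = 0.00158; 0.684 with an estimated correlation), H2-DMa at -0.64, and 15 of 19 hypoxia and glycolysis genes (adjusted p = 0.00295; 0.684 with an estimated correlation), Vegfa at -0.96 and Hk2 at -0.60. None of these genes passed alone. The interferon-gamma list lost its call without trametinib day 3, lead-in trametinib day 3 or trametinib plus anti-PD-L1 day 3 (adjusted p up to 0.596), and the hypoxia list without either of the first 2 (up to 0.124). Over all cells 23 of 26 interferon-gamma genes (adjusted p = 0.0191; 0.998 with an estimated correlation) and 8 of 10 MHC class II genes (0.0234) were lower. Both lost their call with an estimated correlation, and without trametinib plus anti-PD-L1 day 3 (0.547 for each). A term for libraries 7 to 10 leaves the lead-in estimate to the day 0 pair, 1 library against 1, with a doubted label. With it the tests of both lists turned, in macrophages (means 0.0318 and -0.13) and over all cells (-0.0307 and -0.48). A turn with this term describes that pair, not the lead-in after removal of a set effect. CD8 T cells had 6 of 7 MHC class II genes (adjusted p = 7.07e-04; 0.892 with an estimated correlation) and 3 of 3 C1q genes (0.0143) lower, H2-Ab1 at -1.75 and C1qb at -1.33. With the same term the MHC class II test turned here too (mean 0.16), and the C1q list lost its call without trametinib plus anti-PD-L1 day 7 (0.0609). In CD4 T cells these were 5 of 6 (adjusted p = 1.88e-04; 0.439 with an estimated correlation) and 3 of 3, and in regulatory T cells 6 of 6 (adjusted p = 9.48e-07; 0.386 with an estimated correlation) and 3 of 3 (2.20e-06). Naive and progenitor genes were higher in CD4 T cells (9 of 12, adjusted p = 0.00341; 0.771 with an estimated correlation), with Satb1 at 1.87 and Ccr7 at 1.84, and in regulatory T cells (9 of 11, adjusted p = 0.0109; 0.386 with an estimated correlation), with Id3 at 2.49 and Ccr7 at 1.87. In CD4 T cells this test turned with the term for libraries 7 to 10 (mean -0.31), and cluster t14, which expresses Lef1, Tcf7 and Satb1, held 70.2% and 75.0% of the class in lead-in trametinib day 3 and day 7 against 5.97% and 48.7% in the trametinib libraries without the lead-in. In regulatory T cells the list lost its call without lead-in trametinib day 3 or trametinib day 7 (up to 0.0820). CD4 T cells also had 11 of 13 regulatory T effector genes lower (0.0374; 0.439 with an estimated correlation), Ikzf2 at -2.75, and 12 of 17 stress genes higher (0.00639; 0.439 with an estimated correlation). The first of these passed in 5 of 9 fits that leave out a library (adjusted p up to 0.215), and the second was lost without untreated or lead-in day 0 (up to 0.0961). In monocytes 22 of 22 type I interferon response genes were lower (adjusted p = 1.23e-12; 0.138 with an estimated correlation; 0.0212 by fry), and 12 passed when adjusted over the list alone, against 0 over all genes tested. MHC class I (9 of 9), interferon-gamma (23 of 26), chemokine (11 of 14) and cytotoxic genes (5 of 6) were lower in monocytes too, none of them called with an estimated correlation. Without trametinib day 3 the interferon-gamma mean was 0.10 (adjusted p = 0.876), and without it and lead-in day 0 the list was called upwards (mean 0.87, adjusted p = 0.0114). The chemokine and cytotoxic lists were lost without trametinib day 3 (adjusted p = 0.0754 and 0.314), and the cytotoxic test turned with the term for libraries 7 to 10 (mean -0.0597). Monocytes join clusters m6 and m7, and most lay in m6 in 4 of 5 libraries with the lead-in and in m7 in 4 of 5 without it. B cells had 6 list calls and type 2 conventional dendritic cells 3. Over the classes 28 lists were called, 0 with an estimated correlation and 1 by fry.

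**Figure D2:**
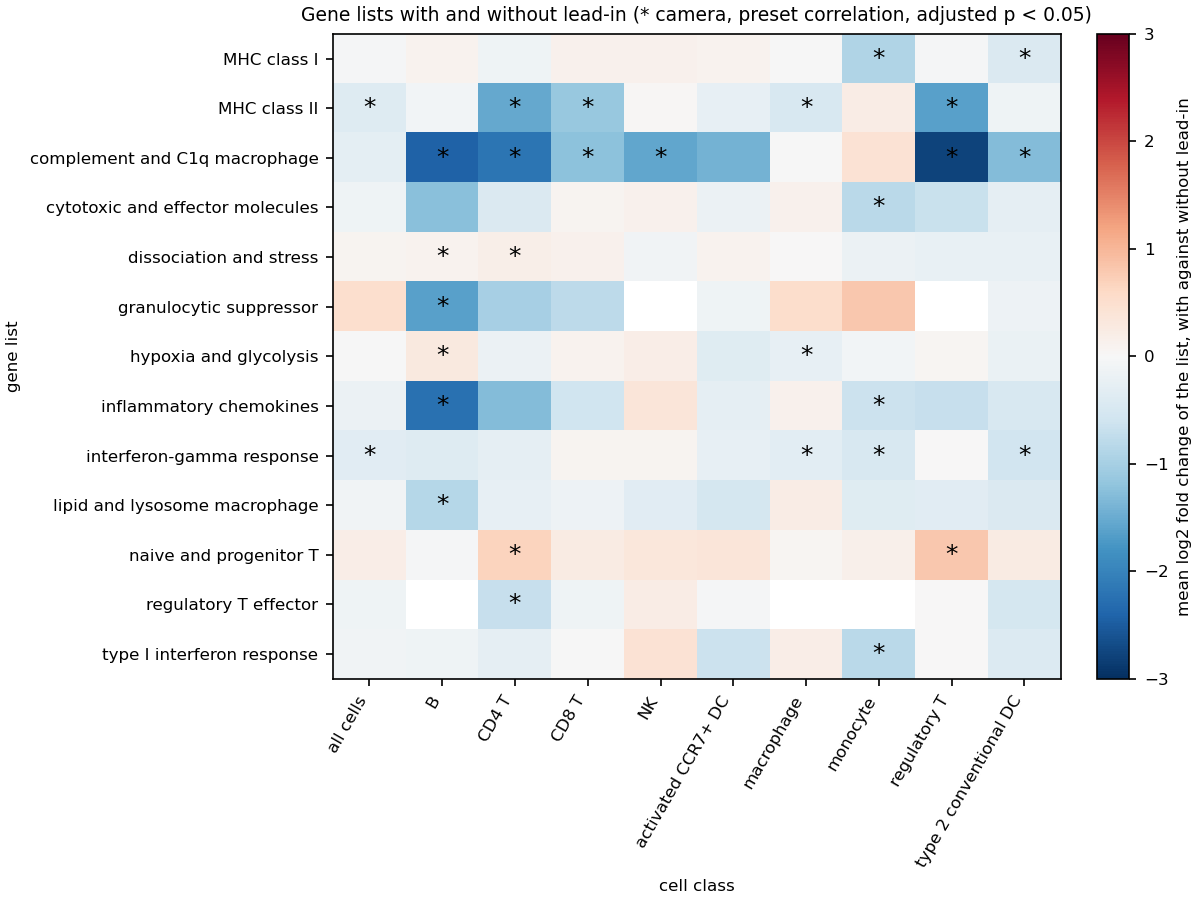
Mean log2 fold change with against without the lead-in of the members of each gene list (vertical axis) in each cell class (horizontal axis), on a colour scale centred at 0. Stars mark lists called by camera with the preset correlation.

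The monocyte share was higher with the lead-in in all 5 pairs, a result that depends on how cells are classed. Monocytes made up 4.06% ± 2.65 of cells with the lead-in and 1.17% ± 1.01 without it (SD, n = 5 each), a mean log2 ratio of 1.98. The exact sign-flip test gave p = 0.0625, the smallest that 5 pairs allow, and 0.675 after adjustment over 18 classes, so this test cannot pass 0.05 for any share. With classes from marker scores of each cell, monocytes were higher in 2 pairs and lower in 3 (mean log2 ratio 0.39), at a clustering resolution of 0.5 and as a share of myeloid cells higher in 4 of 5, and at a resolution of 2.0 in 3 of 5. By limma on log2 odds, no share passed; monocytes stood at 2.02 (adjusted p = 0.32). CD4 T cells (mean log2 ratio 1.20) and CD8 T cells (0.51) were higher in 4 of 5 pairs. NK cells (-0.95) and regulatory T cells (-0.84) were lower in 4 of 5. The day 0 pair was the exception for both CD8 and CD4 T cells: CD8 T cells made up 3.31% of lead-in day 0 cells (interval 2.59 to 4.16) and 16.6% of untreated cells (15.7 to 17.6). As shares of T cells, CD4 T cells were higher in 5 of 5 pairs (0.70) and regulatory T cells lower in 5 of 5 (-1.345). CD8 T cells were then higher in 2 pairs and lower in 3 (0.0047). Some of these counts were small. Lead-in day 0 held 8 regulatory and 21 CD4 among 109 T cells, and trametinib plus anti-PD-L1 day 3 held 12 and 8 among 74. By marker score, as shares of all cells, regulatory T cells were higher in 2 pairs and lower in 3 (-0.51). CD4 T cells were higher in 4 of 5 by that score (0.57).

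**Figure D3:**
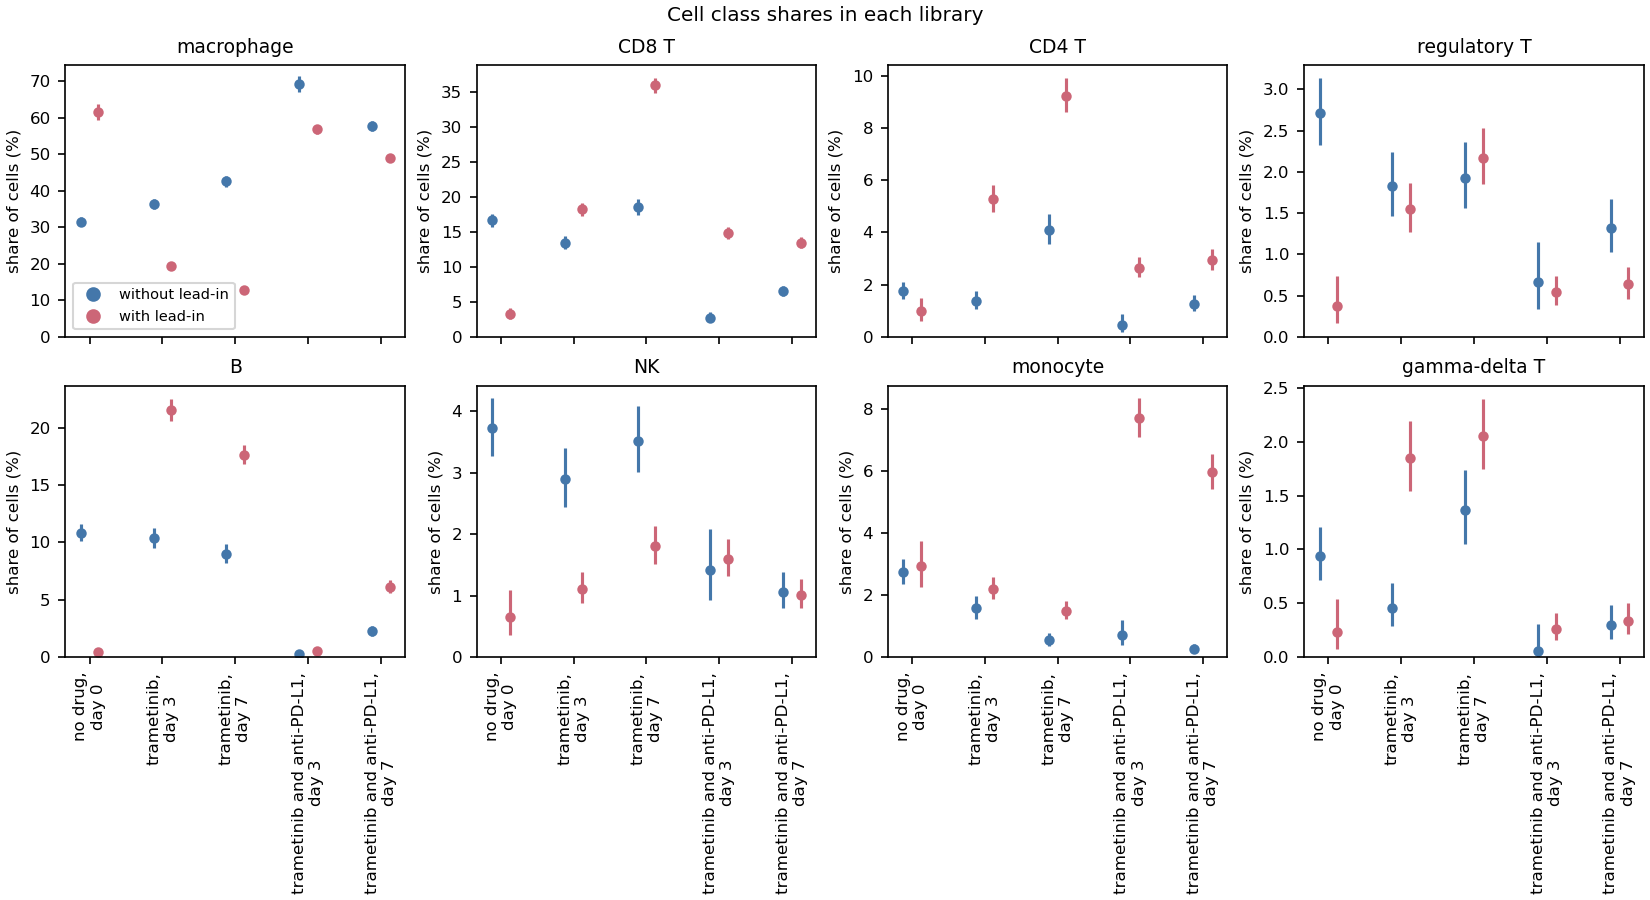
Share of cells of each library in the main classes, in percent, by background, without and with the lead-in, with exact binomial 95% intervals as error bars. The monocyte share is higher with the lead-in in all 5 backgrounds.

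Where anti-PD-L1 was added to trametinib, macrophages made up more of the cells and B and T cells fewer, in every pair of libraries. As lists, cytotoxic, checkpoint and type I interferon response genes lay higher in CD8 T cells and naive genes lower, with no member past the threshold alone (adjusted p = 0.573 for each of the 3 and 0.259 for the naive list with an estimated correlation). The CD8 T cells lay in different clusters: in the lead-in libraries at day 3 and day 7, t9, which expresses Pdcd1 and Tigit, held 6.33% and 4.91% of them with trametinib alone and 28.4% and 18.0% with anti-PD-L1, and t6, which expresses Tcf7 and Satb1, held 19.5% and 26.9% against 5.08% and 13.7%. Without the lead-in t9 held 23.3% and 18.4% against 26% and 45.8%, and t6 1.70% and 8.73% against 6% and 1.20%. In macrophages the type I interferon response list lay higher too (adjusted p = 0.521 with an estimated correlation). Macrophages made up 58.2% ± 8.39 of cells with anti-PD-L1 and 27.8% ± 14.0 without it (SD, n = 4 each; mean log2 ratio 1.21), CD8 T cells stood at 21.5% ± 9.90 without and 9.39% ± 5.72 with anti-PD-L1 (-1.37), and B cells at 14.6% and 2.31% (-3.49). CD4 (-1.48), gamma-delta (-2.50) and regulatory T cells (-1.31) were also lower in 4 of 4 pairs. Each of these 6 had p = 0.125, the smallest that an exact test on 4 pairs allows, and 0.375 after adjustment.

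For single genes, 1 call was made over all classes in this contrast, Aldh1a2 in activated dendritic cells, which makes retinoic acid; without lead-in day 0 and trametinib plus anti-PD-L1 day 3 the sum was 271, of which 262 in CD8 T cells. It had 0 UMIs in the 4 libraries with anti-PD-L1 and 130 UMIs in the 4 trametinib libraries without it, at least 15.3-fold lower against a floor of 3 counts over the group (adjusted p = 0.0199). The call was lost without untreated, trametinib day 3 or day 7, or lead-in trametinib day 3 or day 7 (adjusted p up to 0.481), with no filter on low values (0.372) and with marker-score classes (0.446). Cluster m4 held 14.8% and 45.3% of the class in trametinib day 3 and day 7 and 89.5% and 89.3% in the same libraries with the lead-in, against 0% and 56.4% with anti-PD-L1 and 25% and 56.25% with both. In all cells 0 genes passed by limma, and 2136 had an unadjusted p under 0.05; per class that number ran from 97 to 768. The smallest p in CD8 T cells went to Plscr1 (1.16), Lrmp (0.81) and Pglyrp1 (0.67) upwards and to Ifngr2 (-1.95), Igfbp4 (-2.93) and Nsg2 (-0.95) downwards, all at adjusted p = 0.354. In macrophages they went to Tmem37 (0.73), Vcam1 (0.72), Pex13 (0.56), Ccr7 (-1.68), Tfrc (-0.81) and Nlrp3 (-0.54), and in regulatory T cells to the glucocorticoid response genes Fkbp5 (1.71) and Tsc22d3 (1.26), and to Apoe (1.34), Ninj1 (-2.96), Id3 (-3.62) and Rgs16 (-0.88); none passed. As lists, 18 of 18 cytotoxic genes (camera adjusted p = 8.24e-06; 0.573 with an estimated correlation), 15 of 16 checkpoint genes (1.94e-06) and 19 of 19 type I interferon genes (8.20e-09) were higher in CD8 T cells and 11 of 12 naive genes lower (4.29e-10; 0.259 with an estimated correlation). Among them were Fasl (1.45), Gzmk (1.14), Pdcd1 (1.38), Tigit (1.37), Isg20 (1.34), Cmpk2 (1.13), Klf2 (-1.05) and Ccr7 (-1.64). In macrophages 24 of 24 type I interferon genes were higher (1.89e-15; 0.521 with an estimated correlation), Ifit3b at 0.68 and Ifit3 at 0.63, and 3 of 3 haemoglobin genes (5.71e-06), which red blood cells express. Over the classes 51 lists were called, 0 with an estimated correlation and 0 by fry.

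Trametinib itself was read against only the 2 day 0 libraries, and drug and time since day 0 cannot be told apart. As a list, ERK output genes lay lower in macrophages of trametinib tumours (adjusted p = 0.476 with an estimated correlation), and Arg1 was lower in all 8 comparisons with a matched day 0 library without passing the threshold. In CD8 T cells, cytotoxic genes lay lower and naive genes higher as lists (adjusted p = 0.909 for both with an estimated correlation). By limma 0 genes passed in every class, against a sum of 624 calls with no filter on low values and 567 without trametinib day 3 and lead-in day 0, with 38 to 980 at an unadjusted p under 0.05 per class and 774 in all cells. In macrophages Pparg (0.79), Ift57 (0.65) and Ormdl3 (0.51) led upwards and Mmp12 (-2.11), Ccnb1ip1 (-1.48) and Hmox1 (-0.74) downwards. The CD8 T cell genes Ifngr2 (1.76), Nprl2 (1.31), Spata2 (1.12), Ccnb1ip1 (-2.16) and Cd40lg (-1.97) led; the next lowest is named by a contig and is left out. In regulatory T cells, with 1 day 0 library, Nr4a3 (1.75), Itgav (1.67), Vps37b (1.07), Rln3 (-2.01), Tbrg1 (-1.75) and Ifi27l2a (-1.14) led. Of the lists, 8 of 10 ERK output genes were lower in macrophages (camera adjusted p = 0.00868; 0.476 with an estimated correlation), Dusp6 at -0.69 and Etv5 at -0.65; without the untreated library these 2 stood at 0.17 and 0.36. Antigen cross-presentation genes were higher (10 of 10, adjusted p = 4.13e-04; 0.277 with an estimated correlation), Fscn1 at 1.09. Alternatively activated macrophage genes were called lower (0.00786; 0.277 with an estimated correlation) with a mean of -0.33 and a median of -0.06, led by Arg1 at -1.49 and Retnla at -1.19. Cluster m0, which expresses Retnla, Mgl2, Ear2, Arg1, Ccl17 and Mmp12, held 15.9% of macrophages in the untreated library and at most 2.04% in any other. In CD8 T cells 17 of 18 cytotoxic genes were lower (0.00162; 0.909 with an estimated correlation), Ccl3 at -1.79 and Xcl1 at -0.87, and 9 of 12 naive genes higher (0.00561; 0.909 with an estimated correlation), Ccr7 at 1.36 and Klf2 at 0.84. With an estimated correlation or by fry, 0 trametinib lists were called in any class. Without the untreated library, limma called 1093 genes in CD4 T cells and 130 in CD8 T cells.

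Between day 3 and day 7 of trametinib no single gene passed, and the lists below were called by camera with its preset correlation alone. They draw on the library labelled trametinib day 3, whose macrophages lay 70.15% in cluster a3, which expresses Cxcl9 and Gbp2, against 0.887% at trametinib day 7. All 26 interferon-gamma genes were lower at day 7 in macrophages (camera adjusted p = 0.0432; 0.808 with an estimated correlation), Gbp4 at -0.85 and Gbp7 at -0.62, with 11 of 11 proliferation genes (1.94e-05) and 10 of 10 ERK output genes (0.0469), Ccnd1 at -1.31 and Dusp6 at -0.81. Lipid and lysosome genes were higher (13 of 16, adjusted p = 1.02e-05). In CD8 T cells 21 of 25 interferon-gamma genes (0.0136) and 17 of 19 type I interferon genes (0.00861) were lower. With an estimated correlation or by fry, 0 lists were called for day in any class. Single genes gave 0 calls in every class by limma, with 94 to 344 at an unadjusted p under 0.05 per class and 73 in all cells. Hbegf, a growth factor gene, came nearest in macrophages (-1.17, lower in 4 of 4 pairs, adjusted p = 0.133), ahead of Nfxl1 (-0.57), Eva1b (-0.52), Tmem176a (0.62), Slc2a6 (0.52) and Smim14 (0.47). The CD8 T cell genes Spry2 (0.83), Map1lc3a (0.74), Gpr18 (0.48), Cebpg (-0.73), Clec2d (-0.57) and Ltb (-0.53) led, and in regulatory T cells Aaed1 (2.93), Ube2j1 (1.40), Rgs16 (1.08), Lyz2 (-1.45), H2-Aa (-1.39) and Cd74 (-0.87). Shares of CD4 T cells (mean log2 ratio 0.99), gamma-delta T cells (0.99) and regulatory T cells (0.44) were higher at day 7 in 4 of 4 pairs, and those of monocytes (-0.98), neutrophils (-1.60) and type 2 conventional dendritic cells (-0.35) lower, each at the exact p = 0.125. With classes from marker scores, CD4 T cells (0.62) and gamma-delta T cells (0.54) were higher in 3 of 4 pairs, regulatory T cells (0.29) in 2 of 4, and neutrophils (-0.45) were lower in 3 of 4.

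Whether the lead-in acts otherwise on trametinib tumours than at day 0 was tested as an interaction. With all cells summed, a gene can follow the share of the cells that express it, and T cells made up 5.08% of the lead-in day 0 library and 22.5% of the untreated one. limma called 42 genes over all cells, 31 higher and 11 lower, with 1465 at an unadjusted p under 0.05; Tnfrsf4 stood at 2.52, Tcf7 at 3.40, Vegfa at -2.27 and Hk2 at -1.61. In CD8 T cells 12 genes were called, with Wwp2 at 3.26 and Nrn1 at -2.53, and in macrophages 0, with 736 at an unadjusted p under 0.05. Quantile normalization gave 146 calls in all cells and 0 in CD8 T cells, and summed UMIs gave 105 and 7. These 6 genes were chosen after their values were seen. On the day 0 side the test holds 1 library with and 1 without the lead-in, which the model meets exactly and takes to vary like the others, and the first has a doubted label. The interaction term is the same column as a term for libraries 7 to 10. The lead-in by anti-PD-L1 interaction gave 0 calls in all cells, CD8 T cells and macrophages, with 422, 324 and 732 genes at an unadjusted p under 0.05.

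**Figure D4:**
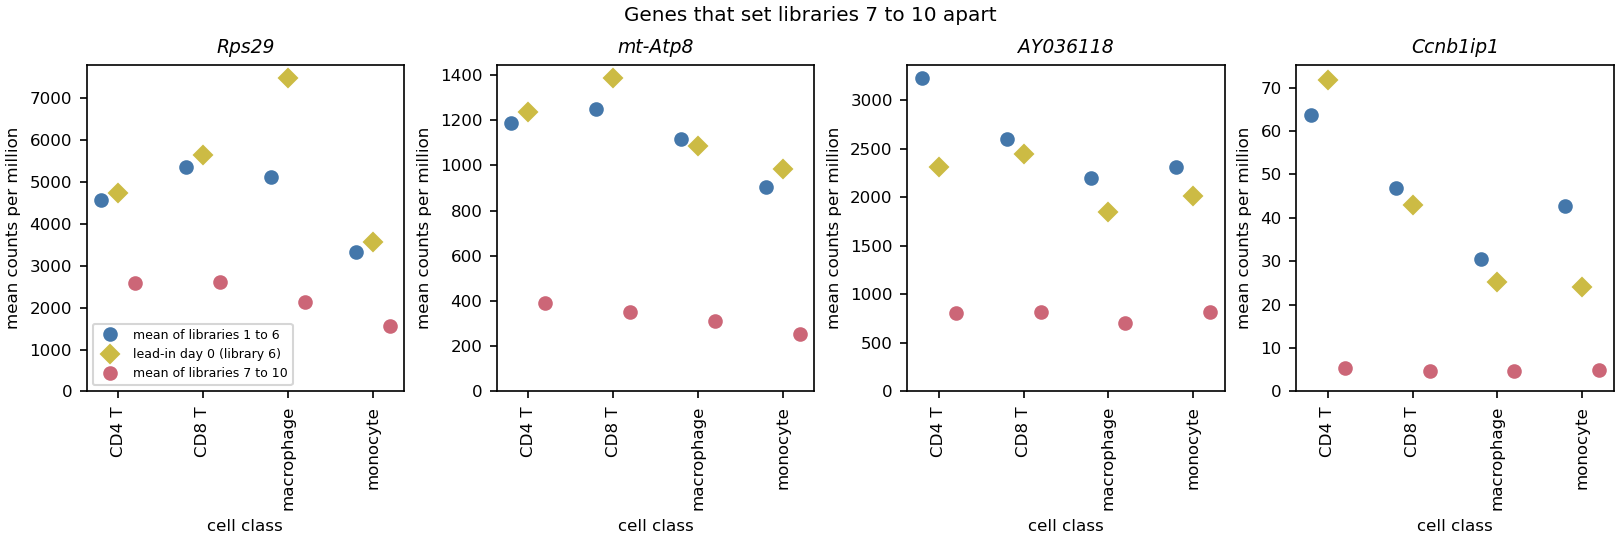
Mean CPM of the 4 genes that lie lower in libraries 7 to 10 than in all other libraries, in the 4 classes that hold the lead-in day 0 library: mean of libraries 1 to 6, lead-in day 0 alone, and mean of libraries 7 to 10. The vertical axes start at 0.

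Macrophages of single libraries were set beside the untreated library without a test, since each is 1 library. Cluster m0, whose leading genes include Retnla, Mgl2, Ear2, Ccl17 and Mmp12, held 15.9% of untreated macrophages and 1.36%, 1.65% and 1.48% in lead-in day 0, trametinib day 3 and trametinib day 7. Cluster a11, whose leading genes include Gdf15 and Ccl8, was the main macrophage cluster in lead-in day 0, while a3 was the main one in the untreated library. Gdf15, a stress-induced cytokine gene, reached 142 CPM in the library labelled lead-in day 0 (Poisson 95% interval 136 to 149) against 11.6 (9.93 to 13.4), 12.3 times the untreated level. It reached 93.2 with trametinib at day 7, or 8.07 times. In the library labelled lead-in day 0, Ccl8 was at 3.95 times and Hbb-bs at 3.63 times the untreated level. Ear2 was lower there (6.97 against 71.6 CPM), as were Mgl2 (21.2 against 206) and Ccnd1 (31.3 against 233). In the library labelled trametinib day 3, the interferon-induced genes Gbp2b and Gbp4 were at 8.25 and 3.74 times the untreated level and Dnase1l3 at 6.21 times, with Ear2 (4.69 against 71.6), Ccl17 (7.42 against 54.0) and Retnla (82.8 against 504) lower. At trametinib day 7 Acp5 was at 6.43 times and Slc25a33 at 4.36 times, with Ear2 (3.87 against 71.6), Mmp12 (4.08 against 61.4) and Plac8 (4.91 against 66.1) lower.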

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

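The comparison of libraries 7 to 10 with the others was chosen after the results had been seen, and so were its tests; the splits of the interactions were written down first. The test of a few genes taking most of the counts replaces one written down first, which left out the 4 genes before scaling (76 calls, against 86 among the other genes) and could decide nothing, since the 4 hold few of the counts. Shares were looked at for a library far from the others of its group in 36 sets of 5 libraries. Chance alone marks about 1 in 20 such sets, and 5 were marked.

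Endothelial-like cells made up 1.75% of the trametinib plus anti-PD-L1 day 3 library, against 0.0394% to 0.412% in the other libraries without a lead-in. They made up 1.59% of the lead-in day 0 library, against 0.0279% to 0.0790% in the other libraries with one. Fibroblast-like cells made up 13.5% of the lead-in day 0 library (interval 12.1 to 15.1), against 0.0658% to 0.804% in the other lead-in libraries. A sort on CD45 should remove both types. Neutrophils made up 4.28% of the lead-in trametinib plus anti-PD-L1 day 3 library, against 0.0466% to 0.568% in the other lead-in libraries. Plasmacytoid dendritic cells made up 0.0466% of the lead-in day 0 library, which is 1 cell, against 0.185% to 0.237%.

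The interaction of lead-in and trametinib passed the threshold in 42 genes of all cells and 12 genes of CD8 T cells; these became 146 and 0 with quantile normalization and 105 and 7 with summed UMIs. On the day 0 side it rests on 1 library with and 1 without the lead-in, both met exactly by the model, and the first has a doubted label. Of 97 splits of the libraries, 4 gave as many genes in all cells and 4 in CD8 T cells, the real one included, but with single libraries at day 0 the splits decide nothing on chance, a judgement made after their values were seen. The split of libraries 2 to 5 is 1 of the 4 and is the same model as the real one. The highest of the other splits gave 305 and 160 genes, several times the real counts, which points to a structure of the samples; what it is was not tested.

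Libraries 7 to 10, the trametinib libraries with a lead-in, differ from all others in 4 genes whatever the class: AY036118, mt-Atp8 and Rps29 lay lower in each of them than in each of the others in 9 of 9 classes, and Ccnb1ip1 in 8 of 9. The lead-in itself stays open as the cause of these 4 genes: the lead-in day 0 library lay above the highest of libraries 7 to 10 in 16 of 16 combinations of gene and class, but the genes were picked for lying lower in libraries 7 to 10 than in all others, that library included, so the test decides nothing. A set effect, such as a separate run, may also lie behind other lead-in calls. This was looked at over the 41 genes called in classes that hold the day 0 pair. Their median difference was 1.26 in that pair, outside the set, against 1.62 within it, all 41 in the same direction. The fits that called these genes include that pair, so its direction and size were part of the selection. CD4 T cells gave 37 of these calls, and lead-in day 0 held 21 CD4 T cells. The comparison therefore leaves the question open. A few genes taking most of the counts would move all other genes of a class by 1 amount, and this is argued against: the largest median of all tested genes in a class was 0.16 from 0, against at least 0.71 for every called gene, and calls went both ways. Sequencing runs and dates of the libraries are not given in the sources used here.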

How the results depend on the processing

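The settings were chosen before the results were seen, except the term for libraries 7 to 10, the 2 fits that leave out 2 libraries each, summed UMIs and the total without unnamed clusters, which were chosen after. Of 2803 values of named genes over all settings, 2399 kept direction and side of the threshold, 317 lost a call, 73 gained one and 14 turned. Leaving out 1 library gave 1221 of 1410 unchanged and 4 turned, and the other settings gave 1178 of 1393 unchanged and 10 turned. A named gene without a call counts as unchanged while it keeps its direction and stays uncalled. These totals therefore do not measure how stable the calls were. With 1 library left out, 153 values lost a call. Alox5ap in CD4 T cells passed in 2 of 9 such fits and Ccnb1ip1 in CD8 T cells in 3 of 10. Lyz2 in regulatory T cells passed in 8 of 8, and AY036118 in NK cells in 9 of 9. Of 337 values of called lists, 275 kept their call, 52 lost it and 10 turned; these leave out an estimated correlation, which kept 0 of the 28 lead-in lists called in the classes, and fry, which kept 1. Of 260 shares 239 stayed within the spread or kept their sign, 4 moved and 17 turned. Of 853 counts of calls 593 stayed within 1.5 times and 260 did not. Among the named genes, none that was called for the lead-in turned under a setting that could be fitted. The settings were not run on other called genes, and the term for libraries 7 to 10 could not be fitted in B, NK, regulatory T or dendritic cells. The cause was not tested for any change below, other than fewer genes tested or fewer libraries. A turn of a list follows the direction of its test, so its mean can keep its sign. Depth differed between libraries by the totals given in the report, and rare classes with under 20 cells in a library were left out of it.

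In all cells the lead-in gave 0 calls in the main results, 1 with classes summed at their mean weight, 8 without trametinib day 3 and lead-in day 0, and 530 without lead-in day 0 and trametinib plus anti-PD-L1 day 3. Leaving out 1 library gave 0 to 144.

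With a term for libraries 7 to 10, lead-in estimates and calls, here and below, rest on the single day 0 pair of libraries. That pair differs in make-up, with T cells at 5.08% of lead-in day 0 and 22.5% of untreated cells. With the term, the lead-in estimate turned in all cells for H2-Ab1 (0.72), Cd274 (0.0848), Cxcl9 (0.35) and H2-DMa (0.18). It also turned in CD8 T cells for H2-Eb1 (0.28) and Tcf7 (-0.85), and in macrophages for Vegfa (0.58) and Hk2 (0.23). List tests turned in all cells for interferon-gamma (mean -0.0307) and MHC class II (-0.48), in CD4 T cells for naive genes (-0.31), in CD8 T cells for MHC class II (0.16), in macrophages for interferon-gamma (0.0318) and MHC class II (-0.13), and in monocytes for cytotoxic genes (-0.0597). Without trametinib day 3 and lead-in day 0, Pdcd1 in CD8 T cells was -0.0769, the interferon-gamma list 0.87 in monocytes and 0.10 in type 2 conventional dendritic cells. Without lead-in day 0 and trametinib plus anti-PD-L1 day 3, Pdcd1 in CD8 T cells was -0.21.

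Lead-in calls per class, where they moved by over 1.5 times. Quantile normalization: B 13, CD4 124, CD8 6, NK 14, activated dendritic 46, macrophage 1, type 2 conventional dendritic 6, sum 248. No filter on low values, with more genes tested: B 0, CD8 0, NK 0, activated dendritic 1, macrophage 0, regulatory T 0, type 2 conventional dendritic 0, sum 43. Marker score of each cell: CD4 9, CD8 0, activated dendritic 1, macrophage 0, monocyte 81, regulatory T 2, type 2 conventional dendritic 0. Block for the matched backgrounds: B 8, CD4 0, CD8 0, activated dendritic 58, macrophage 0, regulatory T 11. Pseudocount 0.1: B 1, CD4 0, CD8 0, activated dendritic 12, regulatory T 18, sum 36. Pseudocount 10: CD4 138, CD8 10, NK 6, activated dendritic 50, regulatory T 55, type 2 conventional dendritic 4, sum 267. Stricter cells: NK 4, activated dendritic 13, type 2 conventional dendritic 3. Doublets removed: type 2 conventional dendritic 3. Term for libraries 7 to 10, in the 4 classes that hold lead-in day 0, where the main count is 41: CD4 824, CD8 18, macrophage 0, sum 842. Without trametinib day 3 and lead-in day 0: CD4 2, NK 4, activated dendritic 11, macrophage 21, monocyte 668, regulatory T 3, type 2 conventional dendritic 0, sum 713. Without lead-in day 0 and trametinib plus anti-PD-L1 day 3: CD4 170, CD8 647, NK 12, activated dendritic 55, macrophage 7, sum 923. Both of these settings leave out lead-in day 0, here and above. Their lead-in libraries are libraries 7 to 10, so the lead-in cannot be told apart from that set. Summed UMIs: CD4 0, CD8 1, NK 10, macrophage 1, regulatory T 62, type 2 conventional dendritic 5.

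Leaving out 1 library gave lead-in calls of 0 to 317 in B cells (317 without trametinib day 7), 0 to 170 in CD4 T cells, 0 to 44 in CD8 T cells (44 without the untreated library), 2 to 12 in NK cells, 2 to 55 in activated dendritic cells, 0 to 9 in macrophages, 0 to 28 in monocytes (28 without trametinib day 7), 3 to 84 in regulatory T cells, 0 to 165 in type 2 conventional dendritic cells (165 without trametinib day 7), and 19 to 683 summed. Anti-PD-L1 calls were 0 to 5 in B cells, 0 to 8 in CD4 T cells, 0 to 1 in NK cells, 0 to 3 in activated dendritic cells, 0 to 1 in type 2 conventional dendritic cells and 0 to 10 summed. Trametinib calls were 0 to 1093 in CD4 T cells, 0 to 130 in CD8 T cells and 0 to 1223 summed. Day calls were 0 to 4 in activated dendritic cells, 0 to 1 in type 2 conventional dendritic cells and 0 to 4 summed. Pdcd1 with the lead-in ranged from -0.0618 to 0.69 in CD8 T cells. With trametinib in macrophages, Dusp6 ranged from -1.56 to 0.17 and Etv5 from -1.65 to 0.36. The interferon-gamma list in type 2 conventional dendritic cells ranged from -0.97 to 0.10.

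Other contrasts. Anti-PD-L1: marker score B 8, activated dendritic 0, sum 8; quantile CD4 7, sum 8; no filter activated dendritic 0, sum 0; term for libraries 7 to 10 CD4 6, sum 7; without trametinib day 3 and lead-in day 0 B 1, CD4 3, activated dendritic 0, sum 4; without lead-in day 0 and trametinib plus anti-PD-L1 day 3 CD4 8, CD8 262, sum 271. Trametinib with no filter: B 1, NK 182, activated dendritic 49, macrophage 1, regulatory T 226, type 2 conventional dendritic 165, sum 624. Trametinib without trametinib day 3 and lead-in day 0: macrophage 30, monocyte 537, sum 567. Day without these 2: monocyte 1, type 2 conventional dendritic 1, sum 2. The lead-in by trametinib interaction gave 105 calls in all cells and 7 in CD8 T cells with summed UMIs, and 146 and 0 with quantile normalization.

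Lists called for the lead-in. An estimated correlation gave 0 in every class, and fry 0 in every class but monocytes (1). Term for libraries 7 to 10: all cells 8, CD4 3, macrophage 8. Without trametinib day 3 and lead-in day 0: all cells 13, CD8 5, NK 0, activated dendritic 5, monocyte 8, regulatory T 5, type 2 conventional dendritic 1. Without lead-in day 0 and trametinib plus anti-PD-L1 day 3: CD8 7, activated dendritic 2, macrophage 6. Leaving out 1 library gave 0 to 9 in all cells, 1 to 7 in CD8 T cells, 0 to 2 in NK cells, 0 to 7 in activated dendritic cells, 3 to 9 in macrophages, 2 to 8 in monocytes, 2 to 5 in regulatory T cells and 1 to 4 in type 2 conventional dendritic cells.

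Shares, as mean log2 ratios. Lead-in: B 0.15 at a resolution of 2.0; activated dendritic 0.0431 and type 1 conventional dendritic 0.00556 as shares of T or myeloid cells; plasmacytoid -0.25 by marker score. By marker score, anti-PD-L1 gave gamma-delta T -1.34, neutrophil 0.96, plasmacytoid 0.16, type 1 conventional dendritic 0.36 and type 2 0.0245, and day gave NK 0.0415, plasmacytoid 0.33 and type 2 conventional dendritic -0.67. Classes with all pairs one way numbered 2 as shares of T or myeloid cells and 0 at a resolution of 2.0. Leaving out 1 pair of libraries, lead-in ratios ranged from -0.45 to 1.06 in B cells, -0.75 to 0.0652 in activated dendritic, -0.92 to 1.09 in cycling myeloid, -1.68 to 0.22 in endothelial, -1.63 to 0.19 in fibroblast and -0.68 to 0.0133 in type 2 conventional dendritic cells.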

Other observations

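The tests in this part were chosen after the results had been seen, except those of the make-up of the macrophage class, of MHC class II in T cells and of the splits of the lists. The test of 3 days of trametinib uses 1 log2 unit as its outer bound and the SD of the other libraries, added after its value was seen, as its inner one; a clause that at least 2% of T cells be called doublets was added to the doublet test after its value was seen.

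ERK output in macrophages goes against the labels of 2 libraries. The library labelled trametinib day 3 lay above the mean of the 7 other trametinib libraries in 8 of 9 classes, and below it by over 1 SD in 0. In CD4 T cells, NK cells and monocytes it lay above by less than 1 SD (0.10, 0.19 and 0.38). In NK cells and CD8 T cells the untreated library itself lay below that mean (-0.17 and -0.10). The library labelled lead-in day 0 lay below the untreated one in 3 of 4 classes. A mislabelled sample may account for this, and the 8 classes leave it open. For the library labelled trametinib day 3, a different make-up of the macrophage class is argued against. Within macrophage clusters that library lay 0.80 above the other trametinib libraries on average. For the library labelled lead-in day 0, the make-up was not tested. That 3 days of trametinib may be too short stays open. In macrophages the highest other day 3 library lay at -0.50 from the library labelled trametinib day 3, between both bounds, and in CD8 T cells, CD4 T cells and monocytes another day 3 library lay above it (0.38, 0.40 and 0.31); each of these had a further treatment.

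The loss of macrophage transcripts from lymphocytes in lead-in tumours may be a matter of free RNA: C1qa, C1qb, C1qc, Apoe and Lyz2 had a median log2 fold change below 0 in 5 of 5 lymphocyte classes, from -1.21 in CD8 T cells to -2.70 in regulatory T cells. In B and NK cells, too, they were lower (-2.31 and -1.57). Doublets are left open, since removing the called ones left the T cell mean at -2.04, but only 50 of 11793 T cells (0.424%) were called. That T cells themselves express less MHC class II is possible: the 4 class II genes measured stood at -0.33 in NK cells, against -2.02 in T cells. Free RNA is not told apart from it. The T cell mean of -2.02 was near that of the 5 macrophage genes (-2.04), while in NK cells these genes fell further than class II (mean -1.57).

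Splits of the libraries into groups of the same sizes were refitted, and the real split is counted among them. For the lead-in calls summed over classes, 15 of 100 splits gave at least the real 99, with 1755 as the highest of the others. Chance is therefore not excluded there, nor in B cells (13 of 95 splits; real 2, highest other 839), CD8 T cells (8 of 100; 2, 227), NK cells (11 of 97; 2, 172), macrophages (7 of 100; 2, 46) or type 2 conventional dendritic cells (9 of 95; 1, 1571). The share of splits lay under 0.05 in CD4 T cells (4 of 98, real 37, highest other 485), activated dendritic cells (2 of 97, 24, 24) and regulatory T cells (4 of 95, 29, 48). These shares are not adjusted over the classes and the splits ignore the matched backgrounds, so they do not exclude chance. In CD4 T cells a block for those backgrounds ended the calls. In the other 2 classes the lead-in libraries are libraries 7 to 10, and the split of libraries 1 and 7 to 10 is the same model as the real one. In all cells (100 of 100; 0, 383), monocytes (96 of 96; 0, 11) and day 7 against day 3 (35 of 35; 0, 750) the real count was 0, which every split reaches, so the splits decide nothing, a judgement made after the values were seen. For anti-PD-L1, 19 of 35 splits gave as many calls (1, 1335). For lists, 82 of 100 splits gave as many for the lead-in (28, 54), 8 of 35 for anti-PD-L1 (51, 64) and 24 of 35 for day (34, 54), so chance is not excluded. Splits with many more calls than the real one point to a structure of the samples, and what drives them was not tested.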
